A study of Sus scrofa with 8 samples.

How the data were processed

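RNA of laser-captured ileal Peyer's patches from 8 crossbred piglets was isolated with the RNeasy Mini Kit, labelled with biotin in a one-cycle reaction and hybridised to Affymetrix Porcine Genome arrays, 1 array per pig, per the labels. The pigs were grouped by the labels into 4 controls, killed before the challenge, and 4 infected animals. The deposited values are on the log2 scale, judged from their range. Their distributions were close but not identical between arrays, with medians from 5.09 to 5.22. Interquartile ranges were 3.75 to 3.86 on the control arrays, 3.85 on infected array a and 3.55 to 3.71 on infected arrays b, c and d. Summarisation, background correction and normalisation methods are not given in the sources used here. The labels give no scan dates or other batches.

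The table held 24123 probe sets, and the 124 AFFX control probe sets were left out of the tests, which leaves 23999. Gene names came from the platform's annotation, updated through the gene table of the RefSeq assembly Sscrofa11.1, which was used for names only. Of all probe sets 10099 had 1 gene symbol, 198 had several and 13826 had none. The gene table changed 0 symbols and left 9989 as they were, and 110 had no match in it and kept the platform's name. Among the tested probe sets 10069 had 1 symbol, for 6774 genes. A probe set without exactly 1 symbol was not named. No depth is given for arrays, so the number of arrays sets the precision. The non-target control probe sets had a median of 2.77 and a highest value of 3.83 on any array, and a group mean up to that value is called within the non-target range.

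Arrays were compared before averaging. Pairs of arrays correlated at 0.972 to 0.993, and at most 73 values were identical between 2 arrays, so each array was counted as 1 replicate.

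Infected and control arrays were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 23999 probe sets and a threshold of 0.05. The fit had no covariate, and dim probe sets were kept. All adjusted p-values of single genes come from limma. SE is that of limma's moderated test, and SD is the spread between the pigs of a group.

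Gene lists for immune responses, cell types and cell processes were fixed before the data were examined, 36 in all. Each gene entered by its probe set of highest mean, and lists with at least 5 members on the array were tested, which holds for 33. The B cell, mast cell and eosinophil, and erythrocyte lists had 4 members each and were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists, and beside it with camera at an estimated correlation and with fry. Per-array means of lists and array quality measures were compared by exact two-sided permutation over the 70 assignments of 4 and 4 arrays, of which the smallest p is 0.0286.

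The genes named were set by a rule before the data were examined. In each direction they are 12 genes that pass, have 1 symbol and do not overlap between the groups, filled by the smallest unadjusted p where fewer pass; as 0 passed, all 24 were filled in this way. To these were added up to 4 members of each described list by smallest p, and 24 key genes of the response to Salmonella, of which 17 had a named probe set. Some key genes are not reported here. The lists whose members are named are those that passed and the interferon-stimulated genes, a choice made after the values were seen. Other members that passed over their list alone are named for completeness, also after their values were seen.

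The procedure was tested on simulated data made from these arrays, with 200 of 23999 probe sets changed in each of 10 runs. It called 72.8% of 2-fold and 95.1% of 4-fold changes, and 5.62% of the calls were false. A shifted list was called in 10 of 10 runs and 0.312% of the unshifted lists were called. Noise was drawn independently for each probe set, with the same SD in both groups, and the lists were random. The rates for probe sets thus do not cover structure shared between probe sets, or genes that vary more in infected pigs. The list rates do not cover lists of correlated genes. Estimated correlations in the tested lists reached 0.787 (interferon-stimulated genes). Dividing the 8 arrays otherwise into 4 and 4 gave up to 1144 called probe sets and up to 16 called lists.

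Alternatives set before the data were examined were quantile normalisation, arrays shifted to 1 median, leaving out the dimmest 40% of probe sets, an intensity trend with robust estimation, array weights and a floor of 32 on the linear scale. The others were the pig letter as a block, leaving out each array in turn, a threshold on the log2 change of 1, a two-group test without moderation, means of all probe sets of a gene, and lists without shared genes. Alternatives added after seeing the data were an adjusted p of 0.10, 1 probe set per named gene, and the 3' to 5' difference and the enterocyte mean as covariates. Leaving out infected pig b with control pig d, and the level of the hybridisation spikes as a batch term, were also added then. The 3' to 5' difference used as a covariate is the mean of those of the ACTB and GAPDH control probe sets.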

Results

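Expression was measured in Peyer's patches, the lymphoid follicles of the gut wall, that had been cut from frozen ileum of 8 weaned crossbred piglets by laser capture. Each pig gave 1 Affymetrix Porcine Genome array. The 4 control pigs were killed on day 0, shortly before the challenge, and the 4 infected pigs were given Salmonella Typhimurium phagetype DT104 by mouth and killed on day 2. The pigs of each group carry the letters a to d, and a letter names different animals in the 2 groups. The deposited table held 24123 probe sets per array on a log2 scale, with array medians from 5.09 to 5.22. The number of arrays limits the precision of every value, and infection cannot be separated from the 2 days between the necropsies.

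The comparison asked which transcripts of the Peyer's patch differ between pigs 2 days after oral Salmonella and uninfected pigs. Transcripts induced by interferon gamma, chemokines and MHC class I genes were higher in the infected pigs, and transcripts of the cell cycle were lower. These list calls rest on camera with a preset correlation, and had adjusted p = 0.155, 0.155, 0.228 and 0.155 with an estimated correlation. The porcine beta-defensin PBD-2, an antimicrobial peptide, averaged 6.02 ± 0.76 in control and 9.86 ± 1.29 in infected pigs (log2, SD, n = 4), a 14.4-fold difference. The T cell attractant CXCL9 was 13.7-fold higher, at 7.20 ± 1.89 against 10.98 ± 1.38, and the interferon-induced GTPase GBP1 was 6.93-fold higher, at 7.58 ± 0.61 against 10.38 ± 1.31. Without infected pig c the PBD-2 difference was 22.4-fold. That of CXCL9 was 22.3-fold without control pig a, 8.14-fold without control pig c and 21.5-fold without infected pig c. None of these single genes passed limma's test after adjustment over all probe sets, with adjusted p = 0.143 for PBD-2, 0.242 for CXCL9 and 0.202 for GBP1. By camera with a preset correlation, 14 fixed gene lists passed as higher and 5 as lower. With an estimated correlation 0 of these 19 passed, with a smallest adjusted p = 0.155.

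Single genes were named by the smallest unadjusted p among named probe sets whose values did not overlap between the groups, 12 in each direction. CCL3L1, a macrophage inflammatory chemokine, differed by 0.95 ± 0.11 on the log2 scale (SE, adjusted p = 0.0830 by limma) and the neutrophil attractant CXCL2 by 1.17 ± 0.15. The class I heavy chains SLA-3 and SLA-8 differed by 1.04 ± 0.13 and 1.09 ± 0.15. The other genes named on the higher side were P2RX4, PBD-2, CCL4, IL18BP, SAA2, PSMB10, IL34 and CATSPER2, with limma adjusted p from 0.143 to 0.191. On the lower side TFDP2, a dimerisation partner of E2F factors, differed by -0.91 ± 0.12 (limma adjusted p = 0.0830), the kinetochore gene APITD1 by -0.83 ± 0.11 and the cold-induced RNA-binding protein gene RBM3 by -1.52 ± 0.26. CAND2, VRK1, PAICS, CXCL12, C3H2orf40, MARCH6, HMGA1, FANCD2 and FABP3 completed the lower side, with limma adjusted p from 0.143 to 0.192. Non-overlap of the 4 control and 4 infected values was a condition for naming these 24 genes, so it adds no support. Of them 0 passed an adjusted p of 0.05 over all probe sets. With 1 probe set tested per named gene, CCL3L1, CXCL2, SLA-3, SLA-8, TFDP2 and APITD1 passed (limma adjusted p from 0.0402 to 0.0430). That setting was added after the data were seen, and it adjusts over 6774 genes in place of 23999 probe sets. Other probe sets of P2RX4, CATSPER2, PAICS, CXCL12 and MARCH6 differed less, for example -0.02 ± 0.29 for the second CXCL12 probe set against -0.85 ± 0.16 for the named one. The probe sets of SAA2, an acute phase protein gene, went in opposite directions, by 2.78 ± 0.49 on the dimmer and -0.63 ± 0.16 on the brighter one.

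**Figure D1:**
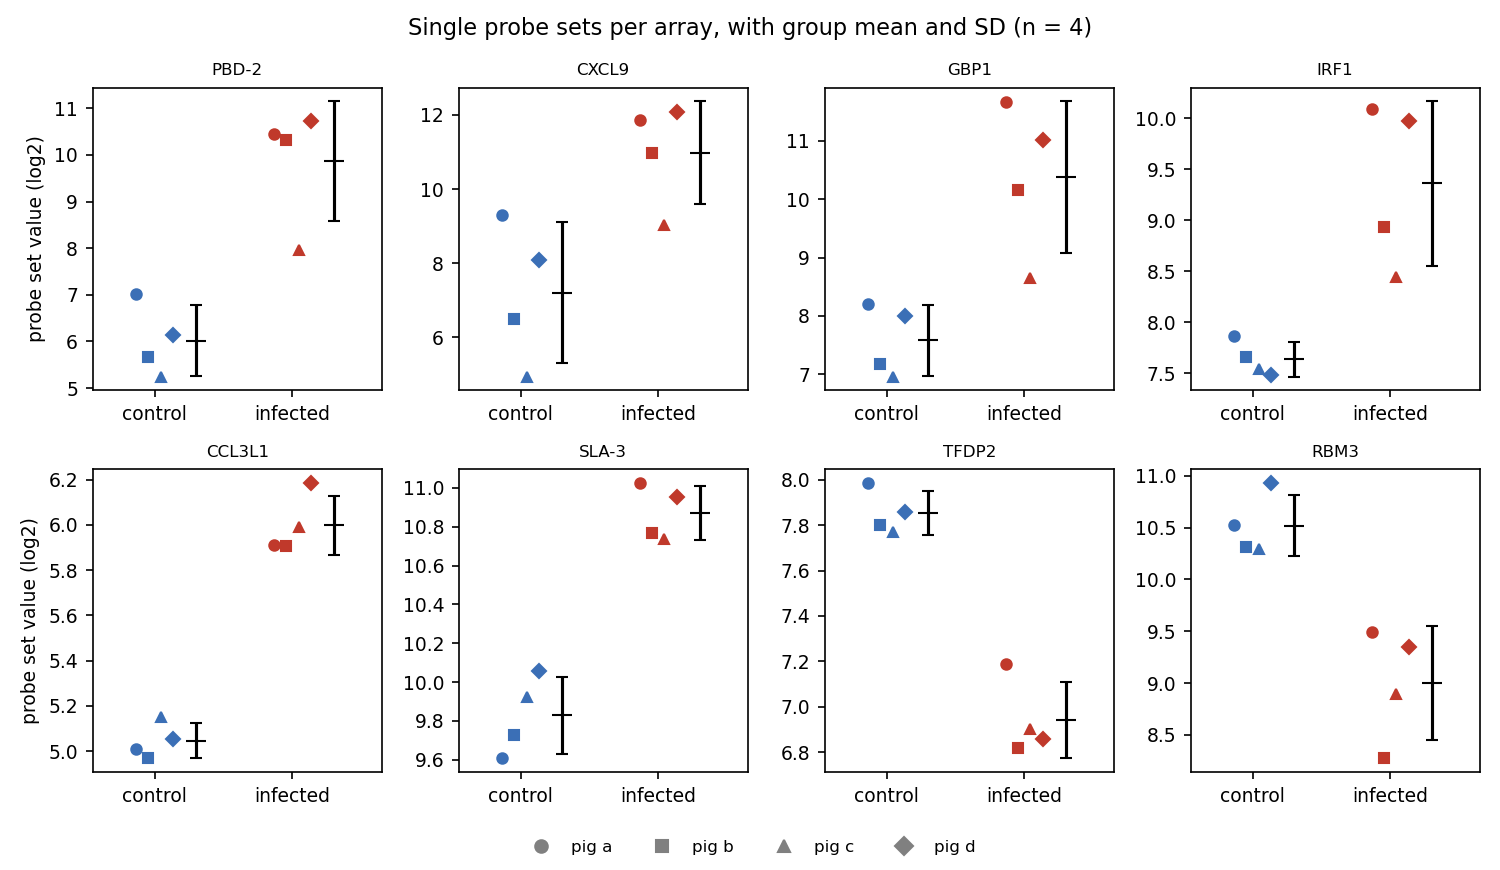
Log2 values of 8 single probe sets, 1 point per array, with the group mean and SD as a bar beside the points (n = 4 per group). PBD-2, GBP1, IRF1, CCL3L1 and SLA-3 show every infected value above every control value, TFDP2 and RBM3 the opposite, while CXCL9 of infected pig c lies below that of control pig a. PBD-2, CCL3L1, SLA-3, TFDP2 and RBM3 were named on the condition that the groups do not overlap.

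Interferon gamma response genes rose as a list. The mean of its 16 measured members went from 7.14 ± 0.21 in control to 8.23 ± 0.49 in infected pigs (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow). All 16 members had a higher mean in infected pigs; 11 rose when adjusted over the list alone and 0 when adjusted over all probe sets. Examples are the transcription factor IRF1 with 1.72 ± 0.33 (SE), the tryptophanyl-tRNA synthetase WARS with 1.07 ± 0.21 and the immunoproteasome subunit PSMB10 with 0.75 ± 0.13. IFNG itself was 0.92 ± 0.25 higher, from a control mean within the range of the non-target probe sets, and GBP2 was 1.21 ± 0.26 higher. The list passed camera at adjusted p = 3.25e-10, and had adjusted p = 0.155 with an estimated correlation. MHC class I presentation genes rose by a mean of 0.48 over 15 members, with 5 rising over the list alone and 0 over all probe sets: SLA-3, SLA-8, PSMB10, the peptide transporter TAP1 with 1.19 ± 0.28, and PSMB8. Camera gave adjusted p = 1.23e-06 for this list and adjusted p = 0.228 with an estimated correlation, and fry ended the call (adjusted p = 0.0580). PSMB10, PSMB8 and TAP1 belong to both lists. Macrophage and enterocyte markers also differed between the groups, with mean changes of 0.40 and -0.60.

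Chemokine genes rose as a list, by a mean of 0.82 over 17 members (camera adjusted p = 8.36e-07, and adjusted p = 0.155 with an estimated correlation). Of these, 7 rose over the list alone and 0 over all probe sets, namely CCL3L1, CXCL2, CCL4 with 1.04 ± 0.17, CXCL9, the neutrophil attractant CXCL8 with 1.89 ± 0.48, and the monocyte attractants CCL2 and CCL8. CXCL2 and CXCL8 lay within the range of the non-target probe sets in the control pigs. Inflammatory cytokine genes rose by a smaller mean of 0.15 over 14 members (camera adjusted p = 0.0305, and adjusted p = 0.186 with an estimated correlation). Over the list alone 4 rose, and 0 over all probe sets: TNF by 0.56 ± 0.13, IL1B by 0.42 ± 0.11, IL12A by 0.77 ± 0.22 and IL15 by 0.72 ± 0.21. That call ended without infected pig a (mean 0.12, adjusted p = 0.115) and without infected pig b (mean 0.16, adjusted p = 0.0566), and also with quantile normalisation, with dim probe sets left out, with array weights and with the floor. IL6 differed by -0.25 ± 0.19, IL17A by 0.21 ± 0.11 and IL10 by 0.19 ± 0.22, and none of these passed. IL6 and IL17A lay within the non-target range in both groups. Antimicrobial and acute phase genes rose by a mean of 0.48 and a median of 0.14 over 16 members (camera adjusted p = 0.00515, and adjusted p = 0.228 with an estimated correlation). PBD-2 and the calprotectin subunit S100A9 rose and the brighter SAA2 probe set fell over the list alone, and 0 members passed over all probe sets. Quantile normalisation, leaving out dim probe sets, the floor, the 3' to 5' difference as a covariate, leaving out infected pig b with control pig d, and fry each ended this call. S100A9 was 1.44 ± 0.36 higher and S100A8 0.70 ± 0.26, both from control means within the non-target range, and S100A8 stayed within it in the infected pigs, at 3.62 ± 0.61 (SD). Markers of monocytes and neutrophils were also higher in infected pigs as a group. The macrophage and monocyte list averaged 6.07 ± 0.03 in control and 6.47 ± 0.29 in infected pigs, and the neutrophil list 4.54 ± 0.04 and 4.91 ± 0.25. The neutrophil list shares S100A8, S100A9, S100A12 and LTF with the antimicrobial list, so these 2 lists are not independent.

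Marker lists of several immune cell types rose. Macrophage and monocyte markers rose by 0.40 over 18 members (camera adjusted p = 9.48e-05, and adjusted p = 0.228 with an estimated correlation). CD83, the adaptor TYROBP and the lysosomal protease CTSB rose over the list alone and 0 members over all probe sets. Without infected pig d the mean was 0.25, and fry ended the call (adjusted p = 0.0907). CD83 was 0.75 ± 0.16 higher, TYROBP 0.88 ± 0.21 and CTSB 0.83 ± 0.24, while the scavenger receptor CD163 at 1.40 ± 0.58 did not pass. CD163 was 9.06 in infected pig d, against 5.77 to 7.12 in the other infected pigs. NK and cytotoxic cell markers rose by 0.40 over 7 members (camera adjusted p = 0.000800, and adjusted p = 0.155 with an estimated correlation). Over the list alone the cytotoxic granule genes GNLY and GZMH rose by 0.69 ± 0.17 and 0.57 ± 0.16 and the Fc receptor FCGR3A by 0.73 ± 0.23, and 0 members rose over all probe sets. Neutrophil markers rose by 0.37 over 11 members (camera adjusted p = 0.00974, and adjusted p = 0.229 with an estimated correlation), with S100A9 rising over the list alone and 0 over all probe sets. This call ended with the floor, without genes shared with another list, with the 3' to 5' difference as a covariate, without infected pig b and control pig d together, and by fry. Dendritic cell markers rose by 0.24 over 7 members (camera adjusted p = 0.00974, and adjusted p = 0.186 with an estimated correlation). Of them 0 passed over the list alone or over all probe sets, and the actin bundling gene FSCN1 differed by 0.48 ± 0.16. MHC class II presentation genes rose by 0.30 over 16 members (camera adjusted p = 0.00414, and adjusted p = 0.386 with an estimated correlation). The costimulatory genes CD40 and CD80 and the proteases CTSB and CTSS rose over the list alone and 0 over all probe sets. CD40 was 0.59 ± 0.12 higher, with 0.30 ± 0.47 and 0.03 ± 0.46 on its dimmer probe sets, and CD80 1.19 ± 0.34. This call ended without infected pig a (mean 0.17, adjusted p = 0.116), and by fry (adjusted p = 0.284). The mean was 0.52 without infected pig b and 0.18 without infected pig d.

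Pattern recognition and inflammasome genes rose by 0.25 over 14 members (camera adjusted p = 0.00515, and adjusted p = 0.155 with an estimated correlation). The receptor of bacterial lipoproteins, TLR2, rose over the list alone, by 1.15 ± 0.24, and 0 members did over all probe sets. TLR4 differed by 0.26 ± 0.16, its co-receptor CD14 by 0.35 ± 0.22 and CASP1 by 0.58 ± 0.26. Regulatory cytokines and receptors rose by 0.23 over 10 members (camera adjusted p = 0.00513, and adjusted p = 0.277 with an estimated correlation). In this list 0 members passed over the list alone or over all probe sets, and TGFB1 differed by 0.53 ± 0.16, with 0.05 ± 0.46 on its dimmer probe set. The floor, the 3' to 5' covariate, leaving out infected pig b with control pig d, and fry each ended this call. Endothelial markers rose by 0.18 over 17 members (camera adjusted p = 0.00362, and adjusted p = 0.155 with an estimated correlation), with the adhesion molecule PECAM1 rising over the list alone by 0.50 ± 0.12 and 0 over all probe sets. Fibroblast and matrix genes rose by 0.17 over 19 members (camera adjusted p = 0.0245, and adjusted p = 0.268 with an estimated correlation), with 0 members passing over the list alone or over all probe sets. This call ended without control pig c (mean 0.12, adjusted p = 0.0926), infected pig b (mean 0.18, adjusted p = 0.0561) and infected pig d (mean 0.11, adjusted p = 0.0727), and also with the 3' to 5' covariate and by fry. The protease inhibitor gene TIMP1 differed by 1.67 ± 0.55 and the matrix proteoglycan gene DCN by -1.16 ± 0.38.

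**Figure D2:**
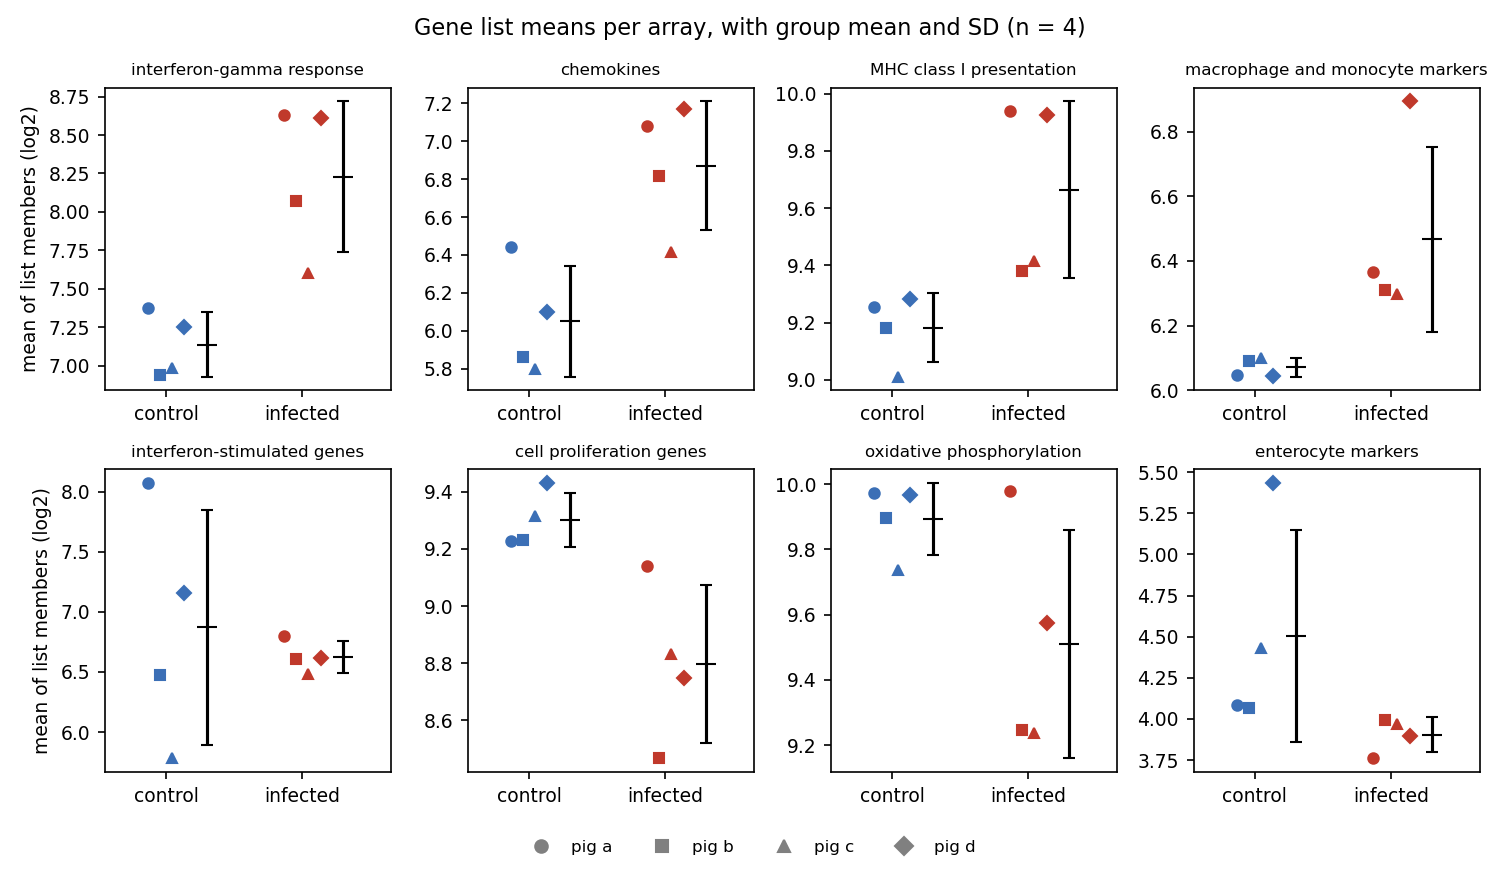
Mean log2 value of the members of 8 gene lists, 1 point per array, with the group mean and SD as a bar beside the points (n = 4 per group). The interferon gamma list of every infected pig lies above that of every control pig, the interferon-stimulated list spreads over the control pigs, and infected pig a lies with the controls for oxidative phosphorylation.

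Cell proliferation genes fell as a list, from a mean of 9.30 ± 0.09 in control to 8.80 ± 0.28 in infected pigs (SD, n = 4; exact permutation p = 0.0286). Of 21 members, 12 fell over the list alone and 0 over all probe sets. Examples are the spindle protein gene NUSAP1 by 0.45 ± 0.10 (SE), the replication helicase subunit gene MCM5 by 0.44 ± 0.11, cyclin B1 (CCNB1) by 0.88 ± 0.24 and UBE2C by 0.68 ± 0.21. Dimmer probe sets differed less for MCM5, by -0.15 ± 0.20 and -0.21 ± 0.13, and for UBE2C, by -0.13 ± 0.20. The dimmer one of NUSAP1 differed more, by -0.73 ± 0.29. Camera gave adjusted p = 1.85e-09 for this list and adjusted p = 0.155 with an estimated correlation. Oxidative phosphorylation genes fell by a mean of 0.39 over 23 members (camera adjusted p = 8.36e-07, and adjusted p = 0.335 with an estimated correlation). Fry ended the call (adjusted p = 0.137). All 23 had a lower mean in infected pigs, while 0 passed over the list alone or over all probe sets. The cytochrome c oxidase subunit COX5B differed by -0.49 ± 0.13 and the succinate dehydrogenase subunits SDHB and SDHA by -0.57 ± 0.21 and -0.33 ± 0.14. The dimmer probe sets of SDHB and SDHA did not fall, with 0.39 ± 0.30 and 0.04 ± 0.17. Cytosolic ribosomal protein genes fell by 0.19 over 37 members (camera adjusted p = 0.000309, and adjusted p = 0.477 with an estimated correlation). Of these, 0 passed over the list alone or over all probe sets. Without infected pig b the mean was -0.11, and quantile normalisation ended the call with a mean of -0.06, as did fry (adjusted p = 0.206). RPL4 differed by -0.33 ± 0.12 and RPL7 by -0.45 ± 0.18, with 0.17 ± 0.14 on the dimmer RPL7 probe set. Glycolysis and hypoxia genes fell by 0.22 over 18 members (camera adjusted p = 0.0298, and adjusted p = 0.348 with an estimated correlation). In this list 0 passed over the list alone or over all probe sets, and the call ended without infected pig a (mean -0.28, adjusted p = 0.0582) and without infected pig b (mean -0.12, adjusted p = 0.0832). It ended in 11 of 23 alternatives, among them leaving out dim probe sets, array weights, the mean of all probe sets of a gene, the 3' to 5' and enterocyte covariates, and fry. The glycolytic enzyme genes TPI1 and GPI differed by -0.75 ± 0.29 and -0.41 ± 0.15.

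Array measures also varied between the pigs beside these lower lists. The log2 difference between the 3' and 5' control probe sets of GAPDH grows as RNA is shortened. It was 4.72 ± 0.67 in control and 5.58 ± 1.25 in infected pigs (SD, n = 4, exact permutation p = 0.343), and reached 7.24 in infected pig b. That of ACTB was 5.41 ± 0.57 and 5.91 ± 0.45 (exact permutation p = 0.229). The lowest values were 4.11 for GAPDH and 4.87 for ACTB, both in control pigs. The 3' bias was thus strong on all arrays, and a small group difference does not show intact RNA. The 5' probe sets of the polyA spikes, transcripts added to the RNA, averaged 5.25 on control array a and 5.77 on infected array b. On the other arrays they averaged 7.89 to 9.07. Control array a and infected array b also had the highest mean 3' to 5' difference, 5.91 and 6.72, against 4.60 to 5.85. This difference thus does not measure RNA degradation of the tissue alone. The hybridisation spikes, added in fixed amount to each array, averaged 9.77 to 10.07 on 3 control arrays and infected array a, and 10.30 to 11.02 on control array c and infected arrays b, c and d. With this level as a batch term the proliferation list changed by -0.39 (camera adjusted p = 1.06e-08) and the oxidative phosphorylation list by -0.18 (adjusted p = 0.00531). The ribosomal list changed by -0.08 (adjusted p = 0.117) and the glycolysis and hypoxia list by -0.14 (adjusted p = 0.110). Within the arrays of lower spike level the single infected pig differed from the 3 controls by -0.16 for proliferation and 0.03 for oxidative phosphorylation. Within the arrays of higher level the 3 infected pigs differed from the single control by -0.63 and -0.38. For the interferon gamma list the within-level differences were 1.44 and 1.11, and for chemokines 0.95 and 1.0. They were 0.70 and 0.56 for MHC class I, 0.30 and 0.40 for macrophage markers, and -0.77 and -0.48 for enterocyte markers. The antimicrobial list changed by 0.46 (adjusted p = 0.115) and the neutrophil list by 0.32 (adjusted p = 0.119) with the batch term.

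**Figure D3:**
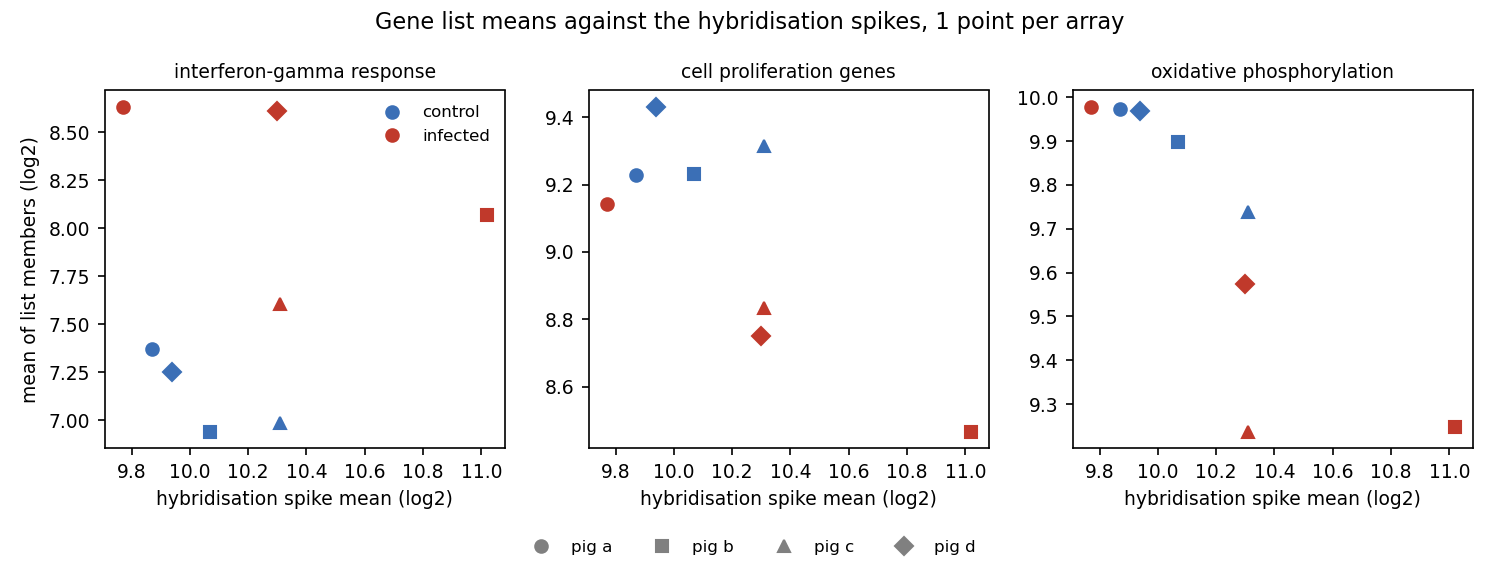
Mean log2 value of 3 gene lists against the mean log2 value of the hybridisation spikes, 1 point per array, blue for control and red for infected pigs. Infected pig a has the lowest spike level, 9.77, and lies with the control pigs for oxidative phosphorylation but above them for the interferon gamma list.

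Enterocyte markers fell as a list, from 4.50 ± 0.64 in control to 3.90 ± 0.11 in infected pigs (SD, n = 4; exact permutation p = 0.0286). Camera gave adjusted p = 0.00530 for this list and adjusted p = 0.493 with an estimated correlation. Of 21 members, EPCAM and the ileal bile acid binding protein gene FABP6 fell over the list alone, by 1.32 ± 0.26 and 3.20 ± 0.74 (SE), and 0 over all probe sets. VIL1 at -1.02 ± 0.39 and APOA1 at -1.70 ± 0.69 did not pass. Control pig d had the highest control value of EPCAM, FABP6, VIL1 and APOA1. It had 5.69 for VIL1 and 8.53 for APOA1, against 3.75 to 4.92 and 4.67 to 5.95 in the other controls. Control pig d had the highest mean of this list, 5.43, and without it the list changed by -0.29. The call ended without infected pig a (mean -0.55, adjusted p = 0.121). It also ended with dim probe sets left out, with low values raised to a floor of 32, where the mean was -0.22, and by fry (adjusted p = 0.295).

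Type I interferon-stimulated genes did not pass, with a mean change of -0.25 over 16 members (camera adjusted p = 0.615) and 0 members passing over the list alone or over all probe sets. Their mean was 6.87 ± 0.98 in control and 6.63 ± 0.13 in infected pigs (SD, n = 4), and the control pigs ranged from 5.78 in pig c to 8.07 in pig a. Without control pig a the list was higher in infected pigs by 0.15 (adjusted p = 0.0226), and without control pig c it changed by -0.61 (adjusted p = 0.00584). Within the arrays of lower and higher spike level it differed by -0.43 and 0.79. ISG15 averaged 7.86 ± 1.92 in control and 6.74 ± 0.30 in infected pigs. The mean of the interferon gamma genes outside the interferon-stimulated list, minus the interferon-stimulated mean, was 0.27 ± 0.79 in control and 1.60 ± 0.39 in infected pigs (SD, n = 4; exact permutation p = 0.0571).

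The lists of T cell markers (mean change 0.08), germinal centre markers (-0.08), plasma cell markers (0.16), M cell and follicle-associated epithelium markers (0.12), and goblet, Paneth and enteroendocrine markers (0.00) did not pass. Neither did those of smooth muscle markers (0.07), enteric nerve and glia markers (0.07), apoptosis and cell death genes (-0.02), heat shock and unfolded protein genes (0.02), immediate early genes (0.08), cholesterol and lipid synthesis genes (-0.09), actin cytoskeleton and bacterial entry genes (-0.18) and lysosome, phagosome and autophagy genes (0.09). The smooth muscle list had a mean above 0 and a median below it. The camera adjusted p of these lists ranged from 0.0879 to 0.926. Leaving out infected pig b made the immediate early (0.14) and lysosome lists (0.22) pass as higher, leaving out infected pig c the plasma cell list (0.22), and leaving out infected pig d the actin list as lower (-0.21). The key genes NOS2 and ICAM1 differed by 0.19 ± 0.15 and 0.40 ± 0.17 and did not pass. IL22, TLR5, CCL20, IDO1, CXCL10 and SAA3 were not analysed here.

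Of 23999 probe sets, 0 passed an adjusted p of 0.05 in limma, with a smallest adjusted p of 0.0830, and 2683 had an unadjusted p under 0.05 (1446 higher and 1237 lower) where chance gives 1200. After shifting the arrays to 1 median, 37.4% of the probe sets at unadjusted p under 0.05 were higher, against 53.9% before. The values of the groups did not overlap for 957 probe sets that were higher and 601 that were lower in infected pigs, 1558 in all against 686 by chance (2.86%). A two-group test without moderation also passed 0. Array weights, of 3.12 for infected pig d and 0.338 to 0.538 for the other infected pigs, passed 2308. Leaving out infected pig a passed 263 and infected pig c 49. Without infected pig a, every infected array was of higher spike level, and among the controls only array c was. At unadjusted p under 0.05 the count without control pig d was 853 higher and 755 lower, without infected pig a 3253 and 2512, and without infected pig d 818 lower. Of the 19 called lists, 13 reached the smallest exact permutation p, 0.0286 (n = 4), in their means per array. The exact permutation p was 0.0571 for chemokines and for glycolysis, 0.114 for ribosomal proteins, 0.143 for oxidative phosphorylation, 0.200 for fibroblast and matrix genes and 0.286 for MHC class II. By fry, 7 of the 14 higher lists and 1 of the 5 lower lists passed, and with an estimated correlation 0 of 33 did, with 8 at unadjusted p under 0.05.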

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

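The comparisons of per-array values within groups were planned, and the tests that weigh explanations for the 3 patterns below were chosen only after the results were seen.

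A value was picked out when 1 pig of the 4 in a group stood apart from the other pigs, by a gap larger than the 95% critical value of Dixon's test. This held for 24 of 256 groups of values, where chance gives about 13. Each gap is given as a share of the range.

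Infected pig a stood apart for P2RX4 (0.972, log2 value 6.0 against 6.29 to 6.30), APOA1 (0.866, 4.27 against 4.35 to 4.37), STAT2 (0.831, 7.54 against 7.70 to 7.74), CTSW (0.836, 4.28 against 4.95 to 5.08) and the mean of inflammatory cytokines (0.935, 5.24 against 5.11 to 5.12). Infected pig b stood apart for HMGA1 (0.984, 8.86 against 9.16 to 9.17), ICAM1 (0.896, 8.49 against 8.95 to 9.0), EPCAM (0.866, 3.82 against 3.33 to 3.39), GPI (0.888, 8.23 against 8.76 to 8.83) and GNLY (0.911, 5.77 against 6.34 to 6.39). Infected pig c was low for PBD-2 (0.848, 7.95 against 10.31 to 10.74). Infected pig d stood apart for TLR2 (0.843, 7.77 against 7.09 to 7.20), NUSAP1 (0.858, 9.88 against 9.94 to 9.95), the mean of macrophage and monocyte markers (0.887, 6.89 against 6.30 to 6.37) and the mean of pattern recognition genes (0.922, 5.79 against 5.59 to 5.61).

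Control pig a stood apart for the dimmer SAA2 probe set (0.895, 5.21 against 3.74 to 3.89), HMGA1 (0.955, 9.57 against 9.71 to 9.72), TNF (0.884, 6.70 against 6.98 to 7.01) and FLT1 (0.887, 3.38 against 3.31 to 3.32). Control pig b was low for CD14 (0.896, 4.02 against 4.32 to 4.35) and S100A9 (0.831, 2.93 against 3.31 to 3.39). Control pig c was low for CXCL12 (0.860, 7.24 against 7.83 to 7.93) and COX5B (0.980, 10.59 against 10.70), and control pig d for SOCS3 (0.881, 3.07 against 3.33 to 3.37).

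The interferon gamma response list was 1.09 higher in infected pigs. It changed by 1.15 (95% interval 0.313 to 1.99) with the 3' to 5' difference as a covariate, by 1.09 (0.147 to 2.02) with the enterocyte mean, by 1.28 (0.523 to 2.03) with the division by hybridisation level and by 1.24 (0.522 to 1.95) with the spike mean. After the slope on the enterocyte mean within the control pigs, 1.14 (0.349 to 1.94) was left. These intervals argue against epithelial tissue or hybridisation level as the whole cause. They also argue against RNA degradation as the whole cause, as far as the 3' to 5' difference measures it. A response to the infection is a candidate explanation that the design allows, and the 2 days between the necropsies stay open as untested.

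Oxidative phosphorylation and proliferation genes were lower by means of -0.39 and -0.50. For proliferation the change with the 3' to 5' difference as a covariate was -0.33 (95% interval -0.53 to -0.13). That interval argues against RNA degradation as the whole cause, as far as the 3' to 5' difference measures it. With the enterocyte mean as a covariate the changes were -0.45 (-0.96 to 0.05) for proliferation and -0.41 (-1.06 to 0.23) for oxidative phosphorylation. After the slopes on it within the control pigs, -0.42 (-0.88 to 0.04) and -0.36 (-0.90 to 0.17) were left. The slopes accounted for -0.09 (-0.13 to -0.04) of the proliferation change and -0.02 (-0.33 to 0.28) of the other. They rest largely on control pig d, with an enterocyte mean of 5.43 against 4.07 to 4.43 in the other controls. Epithelial tissue stays open for both lists, since the intervals of what was left reach 0. The division by hybridisation level, which is the split with the most probe sets and was chosen after that was seen, left -0.39 (-0.80 to 0.01) and -0.18 (-0.53 to 0.18), and the spike mean itself as a covariate left -0.36 (-0.59 to -0.14) and -0.22 (-0.53 to 0.10), so it stays open for both lists, although for proliferation the spike mean argues against it. RNA degradation stays open for oxidative phosphorylation, with -0.25 (-0.74 to 0.24), and so does, untested, a change of cell makeup or activity with infection.

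Enterocyte markers were lower by a mean of -0.60. Of the 21 genes, 19 (90.5%) had their highest control value in control pig d, against 57.1% at the 95th percentile of 10000 random lists. Genes of this list vary together (estimated correlation 0.519) and those of random lists need not, so this share cannot show why control pig d is high. Villus or crypt epithelium caught in that sample may account for part of the difference. Without control pig d the list changed by -0.29. With the 3' to 5' difference as a covariate the change was -0.48 (95% interval -1.48 to 0.52), which leaves RNA degradation open. Loss of epithelium in infected pigs was not tested.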

How the results depend on the processing

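The tests with the 3' to 5' difference, the enterocyte mean or the hybridisation level in the fit, with infected pig b and control pig d left out, at an adjusted p of 0.10 and on 1 probe set per gene were chosen only after the data were seen. As deposited, 0 probe sets passed limma's adjusted p of 0.05, 1446 were higher and 1237 lower at unadjusted p under 0.05, and 14 lists were higher and 5 lower. Array weights, which rest largely on infected pig d (3.12 against 0.338 to 0.538 for the other infected pigs), gave 2308 past the adjusted p, with 4181 higher and 3168 lower unadjusted. A floor of 32 gave 1 past the adjusted p and 690 higher, and leaving out dim probe sets gave 739 higher, with 9 lists higher and 3 lower. An adjusted p of 0.10 gave 6, and so did 1 probe set per gene. Leaving out infected pig b and control pig d gave 13, with 822 higher and 751 lower. The 3' to 5' covariate gave 802 higher and 731 lower. The enterocyte covariate gave 638 and 580, with 3 lists lower; the enterocyte list has no value there, since the covariate is its own mean. The hybridisation batch term gave 3 lists lower. An estimated correlation gave 0 higher and 0 lower lists, and fry 7 and 1.

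Leaving out 1 array at a time gave 0 to 263 past the adjusted p, 853 to 3253 higher, 755 to 2512 lower, 12 to 15 lists higher and 3 to 6 lower. The highest counts of probe sets came without infected pig a, where every infected array left was of higher spike level. Without infected pig c 49 passed. The interferon-stimulated list reversed to 0.15 without control pig a, and was -0.61 without control pig c. With the pig letter as a block 12 probe sets passed, among them PBD-2, CXCL9, GBP1 and CCL2, and 1876 were lower unadjusted; no list call changed. Same-letter deviations correlated at 0.253, 0.0843, 0.499 and 0.0291 for a to d, and pigs a, b and c but not d correlated best with their own letter. The control pigs were killed before the challenge, so a letter names different animals in the 2 groups, and the letters were not used as pairs. As 2 of the 4 correlations are over 0.1, a factor shared by some letters is not excluded. Apart from what the floor, the filter, fewer arrays and the set tests do by construction, the cause was not tested.

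For the named probe sets, 1777 of 1900 alternatives kept their side of the threshold (1 with another sign and 10 with a change of 0) and 123 newly passed, 77 of them with array weights. This count leaves out 1 probe set per gene, where 6 named probe sets newly passed, and other thresholds or tests. For lists, 661 of 751 kept their side, including 29 with another sign in lists that had not passed, 69 lost the call, 20 newly passed and 1 reversed. Genes near the non-target level, such as CXCL8, S100A9 and IFNG in control pigs, have changes limited by background.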

Other observations

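The splits of the arrays were planned, and the batch term for the hybridisation level was chosen only after the splits were seen.

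Several genes outside the rule were picked after their values were seen. The ubiquitin-like modifier UBD, induced by interferon gamma, was 2.45 ± 0.70 higher in infected pigs (log2, SE), and the cytokine signalling inhibitor SOCS1 was 0.50 ± 0.18 higher; both passed over the interferon gamma list alone. The immediate early transcription factor EGR1 was 0.52 ± 0.13 higher and the fatty acid desaturase SCD differed by -0.69 ± 0.18, each the single gene of its list to pass over the list alone. An unnamed probe set had a change of 3.36 and a limma adjusted p of 0.0830. SLC11A1, a metal transporter of phagosomes, differed by 0.70 ± 0.25 and did not pass.

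The 8 arrays can be split into 4 and 4 in 35 ways. All 35 splits reached the real count of 0 probe sets past limma's adjusted p, where the count at unadjusted p under 0.05 was 2683 and array weights gave 2308, and the highest other split gave 1144. At unadjusted p under 0.05, 3 of 35 splits reached the real 2683, with 6606 in the highest other, so chance cannot be excluded for that count. The real split alone, 1 of 35, reached the 19 lists past camera, with 16 in the highest other. For the 2308 probe sets with array weights it was also 1 of 35, with 1828 in the highest other, but the real count rests largely on infected pig d, with a weight of 3.12 against 0.338 to 0.538 for the other infected pigs. A share of 1 in 35 is the smallest that 35 splits can give. It is under 0.05 for each of these counts taken alone. There was no adjustment for the number of counts put through the splits, so chance is not excluded.

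The split with 6606 probe sets set control pigs a, b and d and infected pig a against control pig c and infected pigs b, c and d. This points to a structure of the samples. The hybridisation spikes, cut at their median, gave the same division, 9.77 to 10.07 and 10.30 to 11.02, though their largest gap was from 10.31 to 11.02. Array medians (5.09 to 5.10 against 5.14 to 5.22), interquartile ranges (3.83 to 3.86 against 3.55 to 3.75) and ribosomal means followed it too. So did the first principal component (36.2% of the variance), at -29.0 to -14.5 against 0.97 to 44.7. Which of these made the split was not tested. The spike mean was 10.05 in control and 10.35 in infected pigs (exact permutation p = 0.343, n = 4). With this level as a batch term 0 probe sets passed limma's adjusted p, 1027 were higher and 971 lower at unadjusted p under 0.05, and the plasma cell (0.31), heat shock (0.17), immediate early (0.14) and lysosome (0.15) lists were newly called as higher by camera.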
